A study of Homo sapiens with 12 samples.

How the data were processed

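The series held 12 libraries in 7 groups, taken from the sample labels. H3K4me2 was immunoprecipitated in 3 empty vector and 3 LSD1 knockdown libraries, and LSD1 in 2 wild type libraries. The other 4 libraries, 3 inputs and 1 LSD1 immunoprecipitation from LSD1 knockout cells, were not analysed here, so LSD1 regions could not be set against the knockout. The labels call the libraries of a group replicates but do not say whether they came from separate cultures.

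The values came from 3 deposited region lists, 1 per group, each with a chromosome, start, end, peak name and score per region. Coordinates are on hg38, per the submitters' processing notes, which also name FastQC 0.11.5, Bowtie2 2.3.2, SAMtools 1.9, MACS2 2.1.0, bedtools 2.26.0 and deepTools 3.1.3 without roles or settings. The list names hold both the words merge and intersect. How the libraries of a group were combined is not stated in the sources used here. All peak names of a list carry a single prefix, and a name recurs where a peak was split. The highest peak number was 52905 in the empty vector list, 54395 in the knockdown list and 19408 in the LSD1 list. At least as many peaks were therefore called in the set that gave the names, of which at most 87.5%, 89.2% and 31.3% remained in the lists. The deposited score of a region is the authors' own whole number per named peak, from 13 upwards. What it measures is not given in the sources used here, and it was used only to rank or split regions within a list. If the libraries of a group were intersected, a site missed in 1 library is missing from the list, and regions are trimmed to their common part. Trimming can also leave slivers, and the lists held 240, 190 and 90 regions under 50 bp.

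Lists were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1, counting an overlap from 1 bp. Overlapping H3K4me2 regions of both lists were merged and classed as empty vector only, knockdown only or shared. Shares have exact Clopper-Pearson intervals, the difference of shares a Newcombe interval, and their ratio a log-scale interval. LSD1 regions were placed at random on the same chromosome 1000 times, and 100 times for gene locations, up to the highest coordinate seen on each chromosome; assembly gaps were not excluded, which lowers random overlap. Regions on other contigs were left out of these placements. No p-value was computed between empty vector and knockdown, because the lists hold no value per library.

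Genes came from a RefSeq table of GRCh38.p14, the same build, with 20037 protein-coding genes. The table used here gives gene ends without strand, transcripts or exons, and no genome sequence was used. The planned promoter was therefore replaced by a gene boundary, within 1 kb of either annotated end, which takes in the ends as well as the starts of genes. Exons and introns were not separated, and the planned sequence motifs were not run. A region can lie at the boundaries of neighbouring genes and then counts for each.

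The 14 gene lists, the tests of the comparisons and most alternatives were fixed before the data were examined; alternatives and tests added later are named in the closing section. Each list was set against 10000 random lists of its size from all protein-coding genes, with two-sided p adjusted by Benjamini-Hochberg over the 14 lists; 35 of the 38 interferon response symbols named distinct genes. Genes were named by a rule: the 10 highest scores among knockdown-only genes, among empty-vector-only genes and among LSD1 genes, up to 6 per list with a single-list mark or LSD1, and 13 genes of the study's question, some of which are not reported here. Genes named outside the rule are marked as such. On simulated lists, all 4998 removed, all 3833 added and all 178 LSD1-bound added regions were recovered, and 2 of 20 unrelated lists reached a placement p of 0.05. The full recovery checks the counting of overlaps only. It does not show how shifted edges or split peaks in the real lists affect the single-list classes. Alternatives covered the overlap needed, score and chromosome limits, merging, matched widths, other placements and other gene windows.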

Results

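Chromatin immunoprecipitation followed by sequencing was used to map dimethylated lysine 4 of histone H3 (H3K4me2), a mark of active promoters and enhancers, and the demethylase LSD1 in SW480 cells, an established human colorectal adenocarcinoma line. LSD1, encoded by KDM1A, removes methyl groups from mono- and dimethylated H3K4, and the study's title links it to AKT activity in colorectal cancer with mutant PIK3CA. H3K4me2 was mapped in 3 libraries of cells carrying an empty vector and in 3 libraries of cells with LSD1 knockdown. LSD1 was mapped in 2 libraries of wild type cells. The empty vector list held 49258 H3K4me2 regions with a median width of 1091 bp, the knockdown list 52075 regions with a median width of 1083 bp, and the LSD1 list 6221 regions with a median width of 212 bp. Each list stands for its whole group, so no region has a value per library, no spread between replicates could be measured, and no test between empty vector and knockdown was possible. The read depth behind the lists is unknown, and LSD1 regions were not set against the LSD1 knockout library here. Intervals are exact binomial 95% confidence intervals unless another method is named, and they cover counting error only.

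The first comparison asked which H3K4me2 regions differed when LSD1 was knocked down. Most regions were found in both lists: 44731 of the 49258 empty vector regions, or 90.8% (90.6 to 91.1), overlapped a knockdown region, and 47159 of the 52075 knockdown regions, or 90.6% (90.3 to 90.8), overlapped an empty vector region. The 4527 empty vector regions without a counterpart had a median width of 324 bp, against 1210 bp for the shared ones, and a median score of 55 against 425. The 4916 knockdown regions without a counterpart had a median width of 340 bp against 1184 bp, and a median score of 51 against 352. With a 50% reciprocal overlap required, 80.5% of empty vector and 76.1% of knockdown regions were shared. The knockdown list held 2817 more regions, an excess of 5.72%, yet covered 69.7 Mb against 70.3 Mb, so that the covered length fell by 0.600 Mb. Joining regions within 1 kb of each other turned that difference into an excess of 0.536 Mb for the knockdown, so the lists gave no direction for the extent of the mark.

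The next comparison asked whether the regions found in a single H3K4me2 list lay at sites bound by LSD1. H3K4me2 regions present only in the knockdown overlapped LSD1 regions more often than those present only in the empty vector cells. After both lists were merged, an LSD1 region overlapped 186 of the 4916 knockdown-only regions, or 3.78% (3.27 to 4.36), and 12 of the 4527 empty-vector-only regions, or 0.265% (0.137 to 0.463). The share was 14.3 times as high in the knockdown-only class (95% interval on the log scale 7.97 to 25.6), a difference of 3.52 percentage points (Newcombe 95% interval 2.98 to 4.10). Among the 43027 merged regions built from both lists, 2297, or 5.34% (5.13 to 5.56), overlapped an LSD1 region. Both single-list classes were alike in size, with median widths of 340 bp and 324 bp. The knockdown-only share was the higher one on each of 23 chromosomes (1 to 22 and X). It was highest on chromosome 19, where 23 of 186 knockdown-only regions carried LSD1 against 0 of 138 empty-vector-only regions. Chromosome 20 followed, with 16 of 168 against 1 of 136. On chromosomes 6, 18 and X the excess rested on 1 knockdown-only region with LSD1 against 0 empty-vector-only regions. The size of the ratio depended on the overlap rule. When a 50% reciprocal overlap was needed for a region to count as shared, the shares were 3.92% and 2.44%, a ratio of 1.61 (1.38 to 1.88), and when an LSD1 region within 1 kb sufficed they were 6.61% and 1.66%, a ratio of 3.99 (3.11 to 5.11). These intervals treat regions as independent and do not measure how the lists would vary between cultures.

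**Figure D1:**
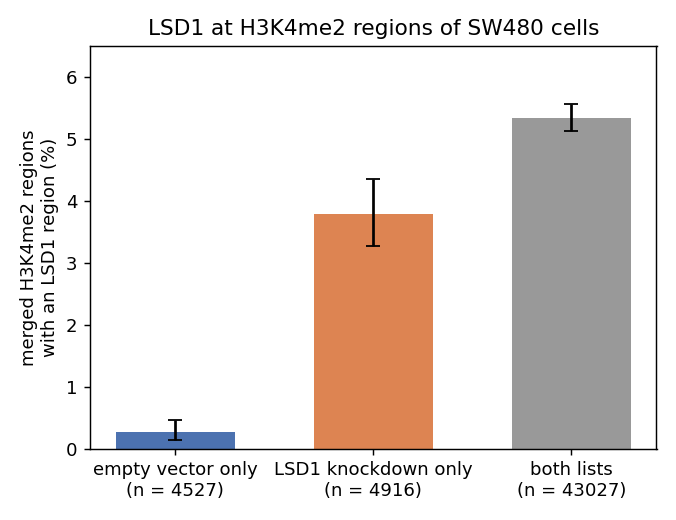
Share of merged H3K4me2 regions (vertical axis, percent) that overlap an LSD1 region, for regions in the empty vector list only, in the LSD1 knockdown list only and in both lists. Bars are shares and error bars exact binomial 95% intervals for counting error; the knockdown-only share of 3.78% stands above the empty-vector-only share of 0.265%.

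**Figure D2:**
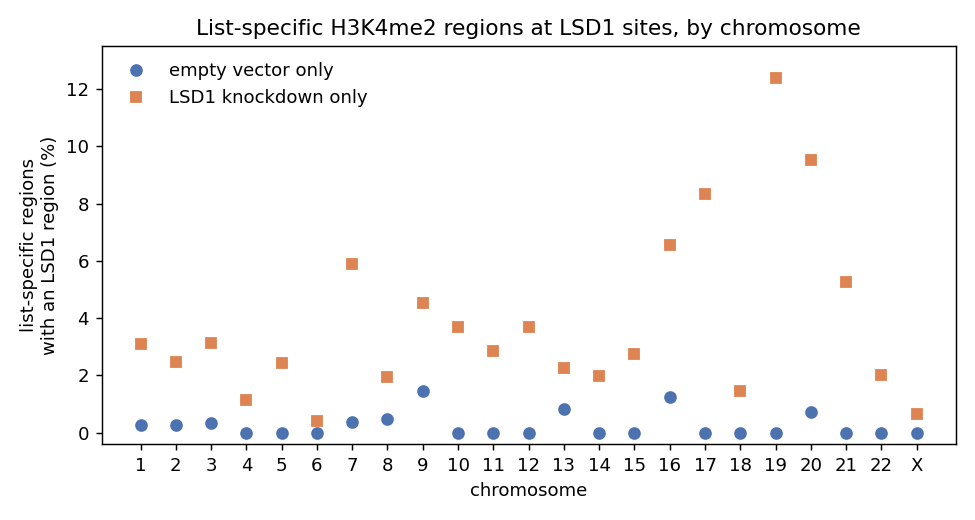
Share of single-list H3K4me2 regions that overlap an LSD1 region (vertical axis, percent) on each of chromosomes 1 to 22 and X (horizontal axis). Circles are empty-vector-only regions and squares knockdown-only regions; the squares lie above the circles on all 23 chromosomes, with 12.4% on chromosome 19 and 0.420% on chromosome 6.

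Seen from the LSD1 list, more LSD1 sites carried H3K4me2 in the knockdown list than in the empty vector list. Of 6113 LSD1 regions on chromosomes 1 to 22, X and Y, 2320, or 38.0% (36.7 to 39.2), overlapped an empty vector H3K4me2 region and 2694, or 44.1% (42.8 to 45.3), overlapped a knockdown region. H3K4me2 was present at 2272 of them in both lists, at 422 in the knockdown only, at 48 in the empty vector only, and at 3371 in neither. Of the 3793 LSD1 regions unmarked in the empty vector list, 11.1% (10.1 to 12.2) were marked in the knockdown list, whereas 2.07% (1.53 to 2.73) of the 2320 marked ones were unmarked there. LSD1 regions placed at random on their own chromosome overlapped the empty vector list in 3.51% of cases on average (range 2.75 to 4.40 over 1000 placements) and the knockdown list in 3.52%. The observed overlap was 10.8-fold and 12.5-fold higher, with a one-sided permutation p of 0.001 for each, the smallest that 1000 placements can give. Random placement within 1 Mb of each LSD1 region left 6.11-fold and 7.13-fold.

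Of the 422 LSD1 regions marked in the knockdown only, 188 lay at a knockdown-only H3K4me2 region and 234 at the edge of an H3K4me2 region present in both lists. At least 50% of the LSD1 region was covered in 299 of the 422, or 70.9%, and in 12 of the 48 marked in the empty vector only, or 25%. The following regions were picked, after the counts were known, as those with the highest LSD1 scores that lay within a gene; their H3K4me2 scores were low, against a list median of 289 in the knockdown. Within ATP9A, a phospholipid flippase gene, LSD1 regions at chromosome 20, 51763947 to 51764367 and 51764549 to 51765023 (hg38), with scores of 700 and 1518, shared 1 knockdown H3K4me2 region from 51763989 to 51764923 with an H3K4me2 score of 41. Within RFX1, a transcription factor gene, an LSD1 region at chromosome 19, 14005411 to 14005689, with a score of 606, lay in a knockdown H3K4me2 region from 14005300 to 14005690 (H3K4me2 score 110). Within AHCY, which encodes adenosylhomocysteinase, an LSD1 region at chromosome 20, 34303476 to 34303928, with a score of 708, met a knockdown H3K4me2 region from 34303535 to 34303950 (H3K4me2 score 90). In the opposite direction, the LSD1 region with the highest score lay within CHN2 at chromosome 7, 29274964 to 29275312, with an empty vector H3K4me2 region from 29273996 to 29275075 (H3K4me2 score 194, list median 331).

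H3K4me2 lay near the ends of genes more often than LSD1 did. A gene boundary was taken as the 1 kb on each side of either annotated end of a protein-coding gene, because strand and transcript starts were not used here. Gene boundaries held 33.8% (33.4 to 34.2) of 49163 empty vector regions, 35.8% (35.4 to 36.2) of 51990 knockdown regions and 14.2% (13.3 to 15.1) of 6113 LSD1 regions. Random placement gave between 3.60% and 4.57%, with a one-sided permutation p of 0.0099 for each list, the smallest that 100 placements can give. The LSD1 share followed the window, with 8.77% within 500 bp and 21.1% within 2500 bp, while the H3K4me2 shares ran from 31.6% to 38.1% in the empty vector and from 32.9% to 40.2% in the knockdown list. A further 37.2% of LSD1 regions had their midpoint inside a gene and 48.7% lay between genes. LSD1 regions at gene boundaries were mostly marked already, with H3K4me2 in both lists at 715 of 866, or 82.6% (79.9 to 85.0). Away from boundaries, 1557 of 5247, or 29.7% (28.4 to 30.9), were marked in both lists, and 387 were marked in the knockdown only against 37 in the empty vector only. At boundaries these numbers were 35 and 11. Among LSD1 regions unmarked in the empty vector list, the knockdown list marked 35 of 140 at boundaries, or 25% (18.1 to 33.0), and 387 of 3653 elsewhere, or 10.6% (9.61 to 11.6).

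Few genes differed between the conditions at their boundaries. Of 20037 protein-coding genes, 13705, or 68.4%, had H3K4me2 at a boundary in both lists, 80 in the knockdown only, 122 in the empty vector only and 6130 in neither. The knockdown-only genes with the highest scores were LOC124905565, the titin gene TTN, the calmodulin-like gene CALML6, C9orf50, TMEM92, MZB1, the ceramidase gene ACER1, the acyl-CoA thioesterase gene ACOT6, the keratin gene KRT6A and BANP. The empty-vector-only genes with the highest scores were the ceramide synthase gene CERS1, the tyrosylprotein sulfotransferase gene TPST1, the transporter gene ABCC11, LOC124904409, the guanine nucleotide exchange factor gene NGEF, the laminin gene LAMC3, the keratin gene KRT77, VSIG10L, the transcription cofactor gene LMO2 and the lipocalin gene LCN6. In 9 of the 10 knockdown-only genes just named, all but ACER1, and in 10 of the 10 empty-vector-only genes, the region overlapped a region of the other list whose edge fell short of the boundary window. At TTN (chromosome 2, 178525989 to 178807423), for example, the knockdown region ran from 178522589 to 178525044 and had a counterpart in the empty vector list. ACER1 (chromosome 19, 6306142 to 6360368) had a knockdown region of 363 bp from 6360999 to 6361361, with a score of 518 and no counterpart.

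Among all single-list genes, the strongest boundary region had no counterpart in the other list at 60 of the 80 knockdown-only genes and at 96 of the 122 empty-vector-only genes. The highest scoring of these, a selection made after the values were seen, were ACER1, R3HDML and OSM, which encodes the cytokine oncostatin M, in the knockdown, with scores of 518, 140 and 119. In the empty vector list they were the alpha-actinin gene ACTN2, the receptor gene GPR85 and RADIL, with scores of 237, 202 and 202. The OSM region covered chromosome 22, 30262998 to 30263429, near the lower end of the gene (30262829 to 30266851). The ACTN2 region covered chromosome 1, 236686537 to 236686825, at the lower end of the gene (236686499 to 236764631). An LSD1 region lay at a boundary of 4 of the 80 knockdown-only genes, or 5%, and of 2 of the 122 empty-vector-only genes, or 1.64%, counts too small to set apart.

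LSD1 occupied the boundaries of 928 of 20037 genes, or 4.63%, and 907 of the 928, or 97.7%, carried H3K4me2 at a boundary in at least 1 list. Both were counted per gene, so LSD1 and the mark could lie at different gene ends or apart within a window. Of the 866 LSD1 regions at boundaries, 105, or 12.1%, overlapped H3K4me2 in neither list. The share with LSD1 was 6.57% of the genes marked in both lists and 0.343% of the unmarked ones. The highest LSD1 scores belonged to ZNF335, a zinc finger gene (score 3854), to VIM, which encodes the mesenchymal intermediate filament vimentin (2399), and to ZEB1, which encodes a repressor of epithelial genes (2148). NR6A1, an orphan nuclear receptor gene, ARHGEF1, the kinase gene PAK4, the mitochondrial chaperone gene CLPB, the phosphodiesterase gene PDE4A, the kinase gene PASK and SGSM1 followed, with scores from 1799 down to 879. The LSD1 region at VIM (chromosome 10, 17228241 to 17237593) ran from 17228226 to 17228743, across the lower gene end and inside an H3K4me2 region of 4692 bp in the empty vector list and of 4626 bp in the knockdown list. At ZEB1 (chromosome 10, 31318417 to 31529804) the LSD1 region ran from 31319252 to 31319745, beyond the boundary's highest scoring H3K4me2 region, which ended at 31318964 in the empty vector list and at 31318875 in the knockdown list. With a window of 500 bp 577 genes had LSD1, with the upper 50% of the LSD1 list by score 534, and anywhere in the gene 2321.

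The genes closest to the study's question were marked in both conditions. KDM1A, its partner gene RCOR1, PIK3CA, AKT1, AKT2, the E-cadherin gene CDH1, VIM, SNAI1, ZEB1, MYC and AXIN2 had H3K4me2 at a boundary in both lists, which does not show whether the amount of the mark differed. LSD1 lay at a boundary of 4 of them, AKT2, VIM, ZEB1 and MYC. The AKT2 region (chromosome 19, 40285726 to 40285975, score 168) lay just beyond the upper end of the gene at 40285345. The MYC region (chromosome 8, 127734101 to 127735111, score 305) ended just before the lower end of the gene at 127735434. MYC lies in a segment of chromosome 8, from 125 to 129 Mb, which was the densest 4 Mb window for LSD1 on chromosomes 1 to 22 and X and held 288 LSD1 regions, 4.63% of the list. The presence of H3K4me2 at KDM1A does not measure the knockdown, since no transcript or protein was measured in these libraries.

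**Figure D3:**
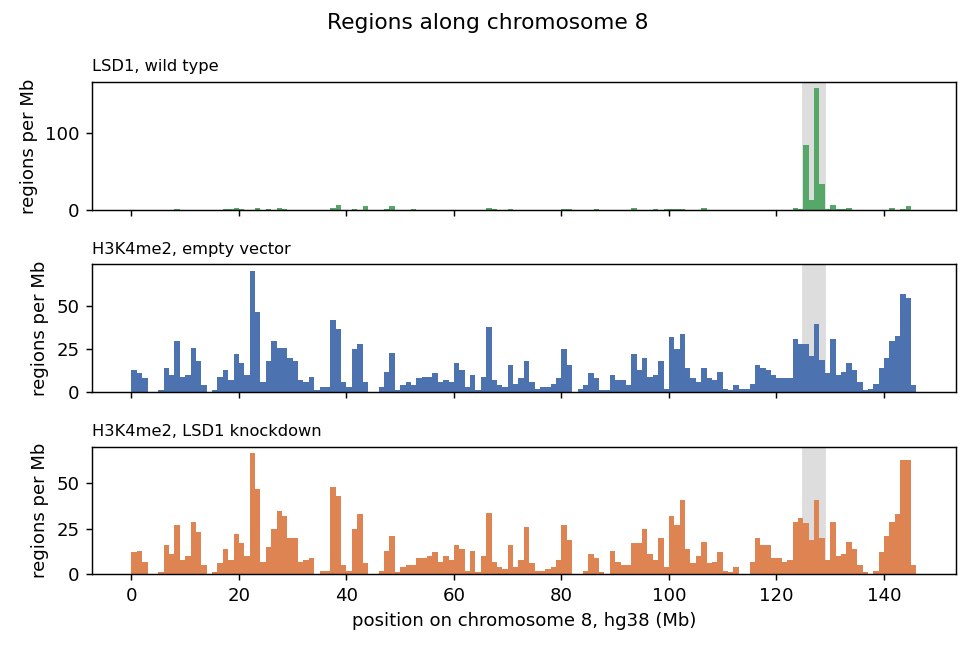
Number of regions starting in each 1 Mb bin (vertical axes, regions per Mb) along chromosome 8 (horizontal axis, Mb, hg38) in the LSD1, empty vector H3K4me2 and knockdown H3K4me2 lists. The grey band marks 125 to 129 Mb, in which 288 LSD1 regions but 108 H3K4me2 regions of each condition start.

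Of the 14 gene lists fixed before the data were examined, mesenchymal genes stood out for LSD1. An LSD1 region lay at the boundary of 7 of 30 mesenchymal genes, or 23.3% (9.93 to 42.3), against a mean of 1.41 in random lists of 30 genes (two-sided permutation p = 0.001 from 10000 random lists; adjusted p = 0.014 over the 14 lists). The 7 genes had 7 separate LSD1 regions. They were VIM, ZEB1, the repressor gene SNAI2 (score 439), the smooth muscle actin gene ACTA2 (321), the receptor kinase gene AXL (168), TGFB1, which encodes a transforming growth factor (62), and FSCN1, which encodes the actin bundling protein fascin and exceeds the 6 names set per list (48). All 7 had H3K4me2 at a boundary in both lists, as did 22 of all 30. The other 13 lists did not pass for LSD1, with adjusted p of 0.318 or above. Closest were Wnt target and intestinal stem genes, with 4 of 25 (NKD1, MYC, RNF43 and DKK1; unadjusted permutation p = 0.0454). PI3K and AKT signalling genes had 4 of 44, namely TSC1, TRIB3, PIK3R2 and AKT2, against a mean of 2.01 in random lists.

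The remaining lists carried LSD1 at few genes. Among LSD1 complex members it was 1 of 23, GFI1B, whose LSD1 region at chromosome 9, 132945255 to 132945612 is also the one counted for the neighbouring TSC1. Among H3K4 methyltransferases and demethylases it was 2 of 19 (SETD1A and DPY30), among epithelial genes 2 of 26 (OVOL2 and EPCAM), among E2F and cell cycle genes 2 of 36 (MCM7 and RRM2) and among ribosomal protein genes 2 of 50 (RPS14 and RPS12). Enteroendocrine and neuronal genes had 1 of 30 (SNAP25) and interferon response genes 1 of 35 (OAS3). Enterocyte and goblet genes had 0 of 30, HOX genes 0 of 39, blood and immune markers 0 of 25, and liver, muscle and lung markers 0 of 25. At these sizes even 0 of 30 leaves shares of up to 11.6% open.

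H3K4me2 lay at all or most genes of the cell cycle, ribosome and chromatin lists and at fewer genes of the enterocyte and goblet, blood and immune, and liver, muscle and lung lists. All 36 E2F and cell cycle genes, all 50 ribosomal protein genes and all 19 H3K4 methyltransferases and demethylases had the mark in both lists, as did 41 of 44 PI3K and AKT genes, 21 of 23 LSD1 complex genes and 34 of 39 HOX genes. These 6 lists lay above random lists, with adjusted permutation p from 0.00056, the smallest reached with 10000 random lists, to 0.0327. Random lists drew genes singly, so neighbouring members that share an H3K4me2 region, as HOX genes may, counted as separate genes. By the same permutation test, 3 lists had fewer genes marked in both conditions than random lists, namely 7 of 30 enterocyte and goblet genes (adjusted p = 0.00056), 11 of 25 blood and immune markers (adjusted p = 0.0311) and 4 of 25 liver, muscle and lung markers (adjusted p = 0.00056). The other 5 lists did not pass, with 22 of 26 epithelial, 22 of 30 mesenchymal, 22 of 25 Wnt target and stem, 22 of 30 enteroendocrine and neuronal, and 28 of 35 interferon response genes marked in both. Members marked in a single list were few: the mucin gene MUC13 and the neurofilament gene NEFL in the knockdown, and the mucin gene MUC2, the phosphatase gene INPP5D and the interferon-induced exonuclease gene ISG20 in the empty vector list. Their scores of 36 to 144 were all below the median of their list, and the MUC2 region had a counterpart in the knockdown list.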

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

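A signal outside the main measurement appeared on contigs other than chromosomes 1 to 22, X and Y. The LSD1 list held 108 regions there, 1.74% of the list, against 95 regions (0.193%) in the empty vector and 85 (0.163%) in the knockdown H3K4me2 list. Among the highest LSD1 scores were also regions on chromosome 3 at 93470443 to 93470727 (score 10962) and on chromosome 5 at 49601227 to 49603033 (score 4111), neither with H3K4me2 in either list. None of these regions was set against the inputs or the knockout library, so whether they reflect LSD1 binding or read mapping was not tested.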

How the results depend on the processing

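No paired analysis was possible because each list pools the libraries of its group and no value per replicate is at hand; leaving out a replicate was likewise not possible. The 5'-most start and the motif alternatives were not run, since strand and sequence were not used here. Alternatives without 125 to 129 Mb of chromosome 8, without regions under 50 bp, within 1 Mb, anywhere in the gene, without counterpart and with the knockdown list lacking its lowest 20% were chosen after seeing the data. In all, 43 values under alternatives kept their side of the test or stayed within the interval or 1.5 times the count, 18 moved and 1 reversed. The share of empty vector regions found in the knockdown was 90.1% with 50% of the shorter region, 80.5% with 50% reciprocal overlap, 98.8% in the upper 50% by score, 88.3% with the same number of regions and 91.5% after joining within 1 kb; for knockdown regions these were 89.9%, 76.1%, 99.2%, 93.0% and 91.3%. The stricter overlaps lower the share by construction. The difference in covered length (knockdown minus empty vector) reversed to 0.536 Mb after joining within 1 kb and was -1.57 Mb with the same number of regions; the cause was not tested. The excess of LSD1 in knockdown-only regions was 4.95 percentage points with LSD1 within 1 kb, 1.48 with 50% reciprocal overlap, 1.82 with the upper 50% of the LSD1 list and 7.43 with the shortened knockdown list (8.03% of 1109 against 0.600% of 10840 regions). The direction was the same throughout, but the ratio of 14.3 fell to 3.99 and 1.61 under the first pair and was 12.8 and 13.4 under the others. Genes with LSD1 numbered 577 with a window of 500 bp, 534 with the upper 50% of the LSD1 list and 2321 anywhere in the gene, as the construction implies. The overlap of LSD1 with H3K4me2 stayed 6.11-fold to 13.4-fold above random placement. The mesenchymal list passed under each alternative run for it, with adjusted permutation p from 0.0056 to 0.0168. These were a window of 2500 bp, random lists from genes with H3K4me2, and leaving out the chromosome 8 segment. The upper 50% of the LSD1 list was not tried for it, and TGFB1 and FSCN1 scored below the LSD1 list median of 86. Its random lists were not matched for local LSD1 density. Unknown depth limits which weak regions could be called in either condition.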

Other observations

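The tests on accessible sites, on the length of shared regions with LSD1 in the part covered in both lists, and on the chromosome 8 segment were chosen after the result was seen; the width match was planned as an alternative, but its use against an explanation was set later. LSD1 regions were unevenly spread over the chromosomes. Per 100 empty vector H3K4me2 regions there were 33.7 LSD1 regions on chromosome 20 and 22.8 on chromosome 19, against 4.17 on chromosome 6 and 1.81 on chromosome X, the lowest. H3K4me2 regions present in both lists also differed at LSD1 sites. In the 2059 shared regions with LSD1 in the part covered in both lists, the median covered length was 1999 bp in the knockdown and 1918 bp in the empty vector list, and 59.5% were longer in the knockdown, against 42.6% of shared regions without LSD1.

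Knockdown-only H3K4me2 regions overlapped LSD1 more often than empty-vector-only ones. After matching on width the share with LSD1 was 3.51% against 0.251%, which argues against wider regions. Among the 1654 and 1579 highest scoring regions of each class the share was 6.89% against 0.380%. The excess was thus not confined to the lowest scores within the classes. Whether near-threshold calls explain it cannot be decided by this split, because both classes scored low as a whole. Their median scores were 51 and 55, against medians of 289 and 331 in the knockdown and empty vector lists. The excess on 23 of 23 chromosomes argues against a few dense segments as its only source. On chromosomes 6, 18 and X, however, it rested on 1 region against 0. A count over chromosomes also cannot show whether the regions crowd into segments within a chromosome. A knockdown list that reaches more sites of any kind could also add gene boundaries. The knockdown list held more boundary regions (18614 against 16606), but 18400 of them overlapped empty vector regions. Fewer separate boundary windows were marked (12945 against 13015). Boundaries made up 4.35% of knockdown-only and 7.27% of empty-vector-only regions. Among LSD1 regions unmarked in the empty vector list, however, the knockdown list marked 25% at boundaries and 10.6% elsewhere. As 5247 of 6113 LSD1 regions lay away from boundaries, this comparison cannot decide whether the knockdown list reached more weak sites there. A candidate explanation is more H3K4me2 around LSD1 sites after knockdown of the demethylase. It was not set apart from a knockdown list that reaches more sites. The test used shared regions with LSD1 in the part covered in both lists, a selection that does not favour the longer list. Their median log2 ratio of knockdown to empty vector covered length was 0.028, above the range of -0.047 to -0.029 in 100 width-matched draws without LSD1. The draws were matched on width alone and came from the same lists. The gain did not grow with LSD1 score, at 12.9% in the highest of 4 score classes and 98 of 894 in the lowest. Variation between the libraries of a group was not measured, since no list gives values per library.

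The dense LSD1 segment on chromosome 8 from 125 to 129 Mb, which holds MYC, had 2.64 LSD1 regions per empty vector H3K4me2 region. The highest of 628 other windows of 4 Mb with at least 20 such H3K4me2 regions had 2.32, on chromosome 1 from 121 Mb. The median of these windows was 0.0601. The segment had been picked as the densest for LSD1 over overlapping positions, whereas the other windows were counted at a single fixed position each. Its rank above them is therefore not a test. Its ratio lay far above the median window, so LSD1 regions in the segment did not simply follow H3K4me2. Of 136 windows with fewer H3K4me2 regions, 3 had a higher ratio or LSD1 without any H3K4me2, with at most 5 LSD1 regions each. A higher DNA copy number may raise calls at any sequence and so lower the marked share, which was 31.6% (26.3 to 37.3) in the segment and 38.3% (37.0 to 39.5) elsewhere in the empty vector list, with intervals that overlap slightly, and 34.0% (28.6 to 39.8) against 44.6% (43.3 to 45.9) in the knockdown list, with intervals that do not. Binding at more unmarked sites would lower the share as well, so copy number and denser binding cannot be told apart; no copy number was measured and the inputs were not analysed here, and no biological explanation was tested.

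A loss of H3K4me2 at interferon response genes was considered because ISG20 and GBP4, the latter named after its values were seen, were marked in the empty vector list only. Within 10 kb of the marked genes of the interferon list there was 1 empty-vector-only region and there were 3 knockdown-only regions, a difference of -2, at percentile 38.3 of random lists. This hypothesis found no support.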
